A study of Homo sapiens with 3 samples.

How the data were processed

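UM-UC-3 cells, a human bladder cancer line, were transfected with a control siRNA or with 1 of 2 siRNAs against the long noncoding RNA DANCR, at 75 nM. RNA was taken after 48 h. Total RNA was amplified, labelled with biotin and hybridised to Affymetrix arrays, with 1 array per group and 3 arrays in all. The siRNA sequences in the labels were UUCUCCGAACGUGUCACGUTT for the control, GCGUACUAACUUGUAGCAATT for DANCR siRNA1 and GAGCUAGAGCAGUGACAAUTT for DANCR siRNA2. The labels gave target positions 390 and 433 for the DANCR siRNAs under a tag that names the coding sequence of WDR5, and which transcript the positions refer to was left open.

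The deposited values were intensities on a linear scale, 1 per probe set and array. The authors had brought the arrays to a common scale by a method that the labels did not state, and the submitters' notes named GCOS 1.4. The 54675 probe sets had values from 1.03 to 9730, with none missing, and array medians of 10.5. In 32.1% of probe sets the value was equal in all 3 arrays (relative tolerance 1e-09), a share that was 14.7% among probe sets with a mean above the median intensity. Above an intensity of 20, 48.7% of values ended in 1 of 3 sets of decimals (0.19619, 0.52953 and 0.86286). The table held 45798 different values among 164025. Such repeats arise when a normalisation maps ranks to shared values, though other causes were not excluded, and they make many log2 ratios exactly 0.

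Probe sets were assigned to genes with the annotation supplied for the array. Of all probe sets, 41097 named a single gene, 1801 named several genes and 11777 named none, and only the first class was used for gene results. The 62 Affymetrix control probe sets were left out of gene results and used for quality checks. The 50th percentile of all values (intensity 10.5) served as a floor: lower values were raised to it, and a ratio with a side at the floor is a bound. A gene counted as measured with at least 1 array above the floor, which left 12436 of 19775 genes. The probe set with the highest mean intensity stood for its gene.

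No p-value was computed for the main comparisons, because each group had 1 array and no replicate check was possible. The number of arrays limits the precision. A gene was called when its log2 ratio to the control was at least 1, or at most -1, with both siRNAs. Each siRNA was also compared with the control, and the siRNA arrays with each other, at the same 2-fold threshold. Both ratios use the same control array, so overlap arises without any effect. It was gauged by counting the genes in which each array in turn lay 2-fold from both others, by 100 simulations of 3 unchanged arrays with the spread of siRNA1 against siRNA2 at each intensity, by the overlap of independent lists and by the covariance of the ratios across genes.

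The 34 gene lists were fixed before the data were examined. The median log2 ratio of each list's measured members was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. A list is described as outside when its median lay below the 2.5 or above the 97.5 percentile. These percentiles describe these 3 arrays and are not tests across replicates. The list of IL11, CCND1 and PLAU was taken from what is known of the study, which chose it on these samples.

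The genes named were also set by a rule fixed before the data were examined. It took DANCR, all members of the lists of study targets and RNA-binding partners, and the 12 genes higher and 12 lower with the largest smaller ratio of the 2 siRNAs. It added up to 4 members per other list by that measure among members with the same direction in both, any member called in both, and the 5 genes most above and most below in siRNA1 against siRNA2. A gene that the rule took among those lower with both siRNAs is not used here. Genes named outside the rule are marked as chosen after their values were seen.

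The procedure was tested on simulated data with 12436 genes. The rule of 2-fold in both arrays recovered 2% of 50 genes planted at 1.5-fold, 76% at 2.5-fold, 92% at 4-fold and 100% at 6-fold. A planted list of 20 genes shifted by 0.5 on the log2 scale lay at percentile 100, and 6 of 100 unshifted lists lay outside the central 95%. The alternatives were median-centring, quantile normalisation, floors at the 30th and 70th percentile, no floor, the median over all probe sets of a gene, probe sets with _s_at and _x_at suffixes left out, and thresholds of 1.5-fold and 3-fold. A limma fit that treats the siRNA arrays as replicates of each other, and the mean of a list's members in place of the median, were further alternatives. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 were used. No off-target search of the siRNA seeds was made, because no transcript sequences were at hand. Genome positions are not given, since the annotation in use did not name its build.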

Results

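Expression was measured on 1 Affymetrix array each for UM-UC-3 bladder cancer cells given a control siRNA, DANCR siRNA1 or DANCR siRNA2. The arrays had mean intensities of 95.3, 96.3 and 96.5, and 49.3%, 49.0% and 48.9% of probe sets lay above the floor. Log2 intensities across all probe sets correlated at 0.992 in each pair of arrays, though probe sets are not independent replicates. The 3'/5' ratio of ACTB was 11.9 in the control, 11.8 with siRNA1 and 14.4 with siRNA2, and that of GAPDH was 1.25, 1.29 and 1.35. The 18 bacterial spike probe sets differed from the control array by at most 0.12 (log2) with siRNA1 and 0.15 with siRNA2, and all 49 measured control probe sets by at most 0.50 and 0.56. With no replicate arrays, all differences below are sizes on these 3 arrays and not tests.

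The first comparison asked whether the targeted RNA was reduced and how the genes tied to it by the study stood. DANCR, a long noncoding RNA, had an intensity of 671 in the control, 116 with siRNA1 and 126 with siRNA2 on its single measured probe set, which is 17.3% and 18.8% of the control. IL11, a cytokine of the interleukin 6 family, was at 102 in the control and 26.2 with siRNA2, 3.87-fold lower, and was at least 9.64-fold lower with siRNA1, where it lay at the floor. CCND1, the G1 cyclin D1, was 2.43-fold lower with siRNA1 and 10.8-fold lower with siRNA2, from an intensity of 1044. PLAU, the urokinase that activates plasminogen, was 5.67-fold lower with siRNA1 and 2.09-fold lower with siRNA2, from 3052. Ranked by the smaller of its differences with the 2 siRNAs, DANCR came first among the genes lower with both.

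All 3 members of the list IL11, CCND1 and PLAU were at least 2-fold lower with both siRNAs. The study chose these genes on these samples, so the list is not independent evidence of its direction. A further probe set of CCND1 gave log2 ratios of -1.14 and -2.75, and that of PLAU gave -2.72 and -1.44. The further IL11 probe set had intensities of 42.2, 30.5 and 31.5 and ratios of -0.47 and -0.42, short of 2-fold. The knockdown values in the labels differed from the array ratios of DANCR by 7.02e-06 and 4.06e-05, so they are not a separate measurement. LRPPRC, an RNA-binding protein of mitochondrial mRNA, had log2 ratios of 0.14 and 0.45, its partner SLIRP -0.11 and 0.10, and the chromatin protein WDR5 0.01 and -0.41. The median of these 3 genes was 0.01 with siRNA1 and 0.10 with siRNA2, inside the random lists.

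**Figure D1:**
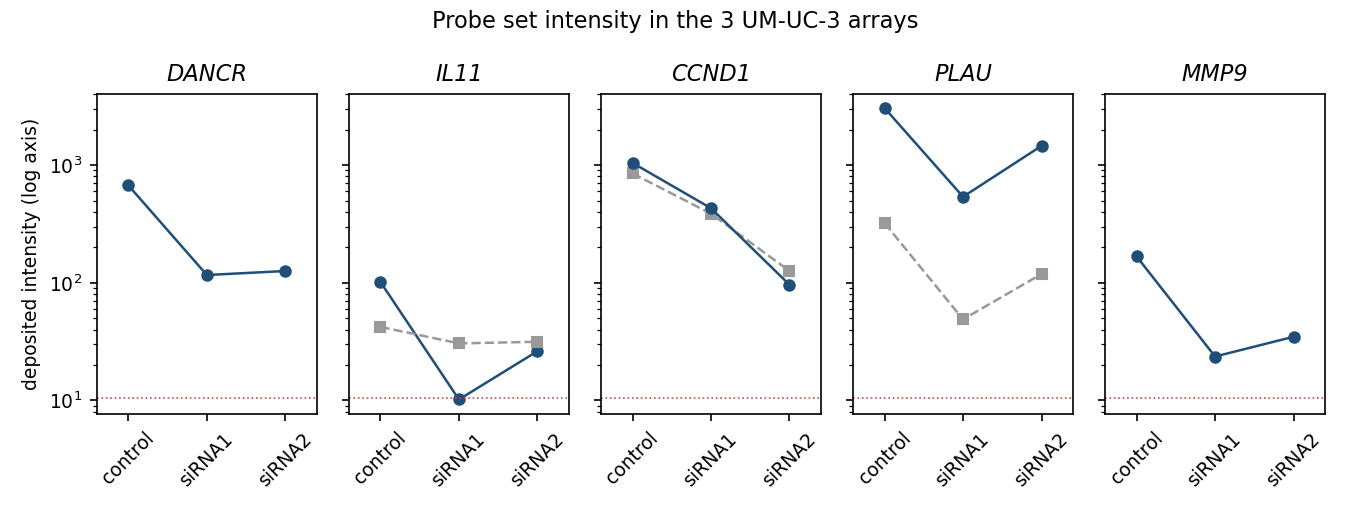
Deposited intensity (log axis) of DANCR, IL11, CCND1, PLAU and MMP9 in the control, siRNA1 and siRNA2 arrays, 1 array each. Circles show the probe set that stands for the gene, grey squares a further probe set and the dotted line the floor at 10.5. DANCR went from 671 in the control to 116 and 126.

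The second comparison asked which genes moved the same way with both siRNAs, as the study selected them. At the 2-fold threshold 89 genes were higher and 35 were lower with both siRNAs than in the control. Among the lower genes, MMP9, a matrix metalloproteinase that degrades basement membrane collagen, was 7.08-fold lower with siRNA1 and 4.81-fold with siRNA2. RAB8B, a small GTPase of vesicle traffic, was 3.02-fold and 3.99-fold lower. Among the higher genes, the protocadherin PCDH10 was 2.82-fold and 5.26-fold higher and the arginine methyltransferase PRMT6 was 3.42-fold and 4.85-fold higher. The collagen gene COL3A1 was at least 4.74-fold and at least 5.85-fold higher, from a control at the floor, with intensities of 49.9 and 61.6.

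The remaining named genes in this group were of low to moderate intensity. Lower with both were FRMD4A, a scaffold protein (-2.48 and -1.45 on the log2 scale), CLGN, a chaperone of the endoplasmic reticulum (-2.15 and -1.58), TMCC3 (-1.94 and -1.51), ECSCR (-1.74 and -1.79), MIR100HG, a microRNA host transcript (-1.66 and -1.53), P2RY8, a G-protein-coupled receptor (-1.59 and -1.41), and the kinase HIPK3 (-1.51 and -1.66). Higher with both were EGR1, an immediate early transcription factor (2.31 and 1.53), ZNF227 (2.08 and 1.92), LINC01234 (1.74 and 1.61), SAMSN1 (1.67 and 1.55), FMC1 (1.65 and 1.62), MFN1, which fuses mitochondrial outer membranes (1.48 and 1.59), SLC17A5, a lysosomal sialic acid transporter (1.47 and 1.88), and the secreted guidance factor SEMA3A (1.45 and 2.05). PCDH9, a second protocadherin, was 5.53-fold and 4.83-fold higher, but its other probe set pointed the other way, with ratios of -0.36 and -0.14. The other probe sets of EGR1 lay near the floor and gave 0.10 and 0.00, and 0.83 and 0.25. By the median over their probe sets, FRMD4A (-0.73 with siRNA2), SLC17A5 (0.78 with siRNA1), SEMA3A (0.94 with siRNA1) and EGR1 (0.25 with siRNA2) fell short of 2-fold, and SAMSN1 (0.54 and 0.48) did so without _s_at and _x_at probe sets. With the floor at the 70th percentile, COL3A1 (0.74 with siRNA1), ECSCR (-0.54 with both), P2RY8 (-0.58 with both) and SAMSN1 (0.25 and 0.13) fell short.

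The size of this set was set against what a shared control array gives. The control array lay 2-fold from both others in 124 genes, siRNA1 did so in 128 and siRNA2 in 135. By direction, the control lay above both others in 35 genes and below in 89, siRNA1 above in 35 and below in 93, and siRNA2 above in 65 and below in 70. Simulated unchanged arrays gave a median of 117 genes in both (central 95% 96.9 to 139), with 54 higher and 64 lower. The observed 89 higher genes lay above the simulated range of 39.5 to 68.5, and the observed 35 lower genes lay below that of 48.5 to 76.1. Across genes, which are not independent replicates, the 2 log2 ratios correlated at 0.48, against 0.50 in the simulation, and their covariance was 0.0804 against 0.0874. Among genes with neither ratio exactly 0, the share with the same sign in both, 70.6%, lay above the simulated 68.4% (67.4% to 68.9%). Of all measured genes, 29.2% were higher and 23.7% lower in both. The simulation was not matched on how many ratios were exactly 0. Independent lists would share 4.98 higher and 2.65 lower genes. The count of shared genes was therefore no larger than the counts with either siRNA array set apart.

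**Figure D2:**
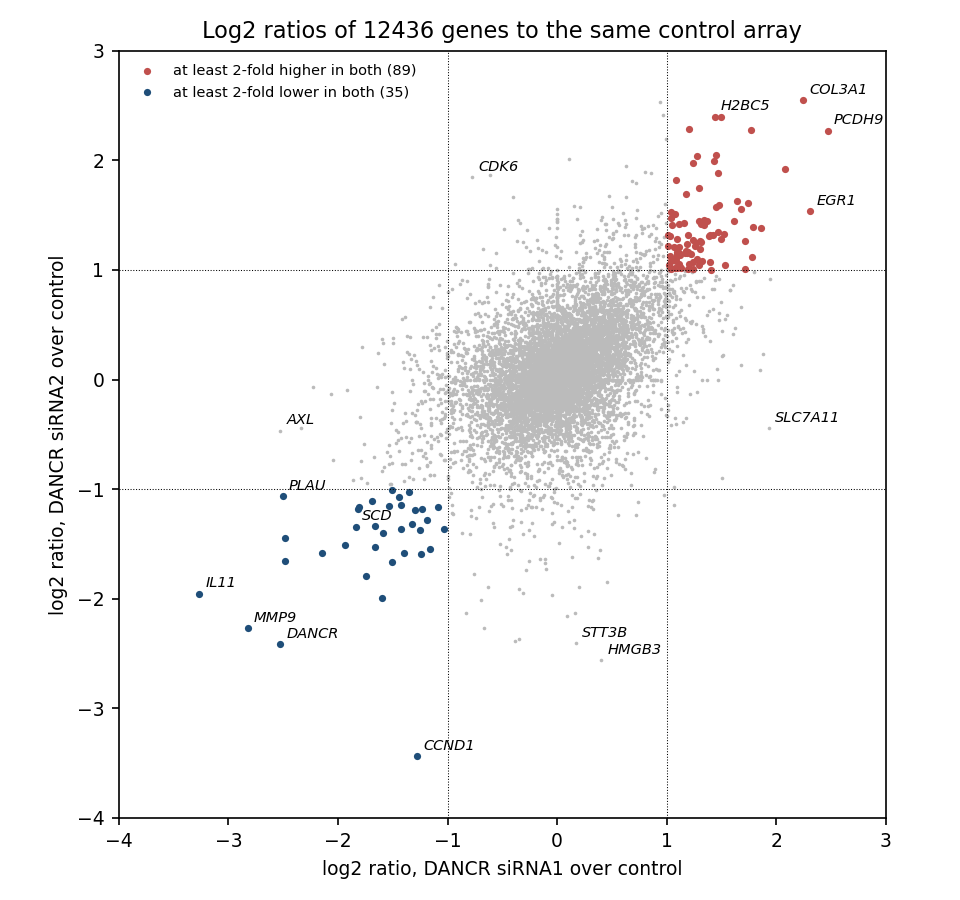
Log2 ratio to the control with siRNA1 (x axis) and siRNA2 (y axis) for 12436 genes, each a point, both against the same control array. Red points are the 89 genes at least 2-fold higher and blue points the 35 genes at least 2-fold lower in both, and dotted lines mark 2-fold. DANCR, IL11, CCND1, PLAU and MMP9 lie in the lower left.

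**Figure D3:**
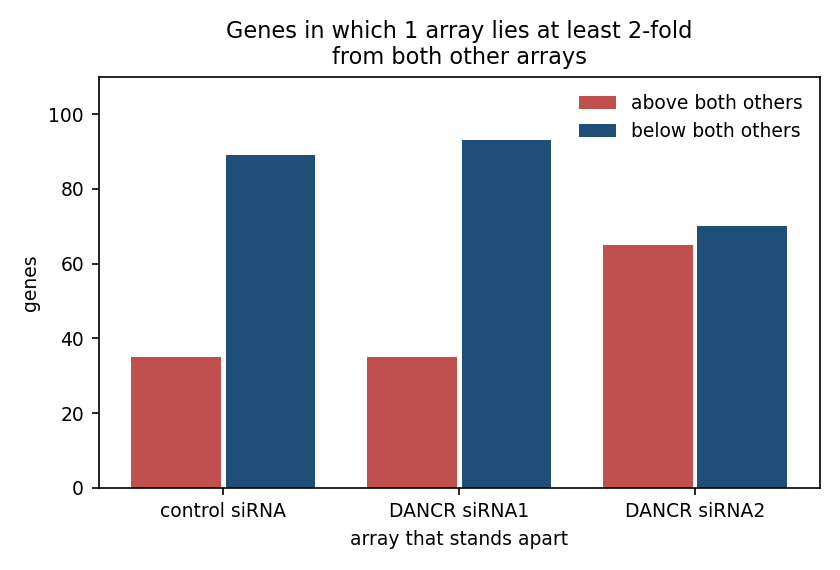
Number of genes (y axis, from 0) in which the array named on the x axis lay at least 2-fold above (red) or below (blue) both other arrays. The totals were 124 for the control, 128 for siRNA1 and 135 for siRNA2.

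Of the 34 lists, 7 had medians outside the random lists on the same side with both siRNAs, 6 lower and 1 higher. These lists, too, rest on the single control array. The study targets are 1 of the 6. NF-kappaB targets and chemokines had medians of -0.54 with siRNA1 and -0.28 with siRNA2, with 12 of 14 measured members lower in both. CXCL3, a neutrophil chemokine, was 2.37-fold and 3.01-fold lower, and NFKBIA, the inhibitor that NF-kappaB itself induces, had ratios of -1.32 and -0.67. CXCL8 had -0.73 and -0.53 and CXCL2 -0.54 and -0.52. Cholesterol synthesis genes had medians of -0.34 and -0.30, with 13 of 16 lower in both and none 2-fold lower in both. ACAT2, a thiolase, had ratios of -0.58 and -0.61, MSMO1 -0.48 and -0.45 and NSDHL -0.38 and -0.38. IDI1, which isomerises isopentenyl diphosphate, had -0.85 and -0.66, and its other probe sets gave -0.53 and -0.53, 0.00 and 0.56, and -0.12 and 0.09.

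Plasminogen activation and matrix protease genes had medians of -0.21 and -0.15, with 6 of 13 lower in both, and with PLAU and MMP9 at 2-fold in both. PLAU is a study target chosen on these samples, so this list is not independent of that choice, and its call without PLAU was not computed. With siRNA2 its median was the value of TIMP1 (-0.15). The next higher member, TIMP3, was at 0.00, and the random range began at -0.11. PLAUR, the urokinase receptor, had ratios of -0.83 and -0.65, and PLAT, the tissue plasminogen activator, -0.50 and -0.50. Cyclins and their kinases and inhibitors had medians of -0.19 and -0.15, with 10 of 15 lower in both and CCND1 at 2-fold in both. CCND1 is also a study target, and the call of this list without it was not computed. CCNE2, cyclin E2, had ratios of -0.78 and -1.25 and CDKN1A, the inhibitor p21, had -0.82 and -0.70. DNA replication genes had medians of -0.09 and -0.35, and by the mean of members (-0.07 with siRNA1) they lay inside the random lists with siRNA1. Leaving out probe sets with _s_at and _x_at suffixes ended the calls for proteases (-0.0209 against -0.07 in the mean of both siRNAs), cyclins (-0.19 against -0.19) and replication (-0.14 against -0.23). Only the unfolded protein and integrated stress response list was higher with both, at 0.76 and 0.23, or 0.53 in the mean of both. Its call also ended without those probe sets, though its median stayed at 0.53, and with the median over probe sets (0.48). DDIT3, a stress transcription factor, had ratios of 1.94 and 0.91, and SESN2 1.28 and 0.75. PSAT1, an enzyme of serine synthesis, had 1.05 and 0.52, though its other probe set gave 0.63 and -0.26. The chaperone HSPA5 had 0.48 and 0.57, though its other probe set gave -0.47 and -0.43.

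The third comparison took each siRNA against the control. With siRNA1, 232 genes were at least 2-fold higher and 218 lower, a balance that turned under quantile normalisation (215 and 236), the 70th percentile floor (172 and 175), the median over probe sets (148 and 151) and a 3-fold threshold (24 and 36). Its stress response list had 8 of 23 members 2-fold higher, against 1 of 23 with siRNA2. TRIB3, CHAC1 and ASNS, all induced by stress signalling and chosen here after their values were seen, had ratios of 1.51, 1.88 and 1.02 with siRNA1, and 0.22, 0.24 and 0.19 with siRNA2. YAP/TEAD targets had a median of -0.30 with siRNA1, with 12 of 15 lower, and 0.10 with siRNA2. AXL, a receptor tyrosine kinase, was at 1290 in the control, 224 with siRNA1 and 934 with siRNA2. Its other probe set, at an intensity of 43.9 in the control, gave -0.76 with siRNA1. Immediate early and ERK feedback genes had a median of -0.24 with siRNA1 and 0.00 with siRNA2. There IER3 had ratios of -1.06 and -0.69 and JUNB -0.41 and -0.38, whereas EGR1 was higher.

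With siRNA2, 267 genes were at least 2-fold higher and 151 lower, on the array with the highest 3'/5' ratios of ACTB (14.4) and GAPDH (1.35). G2/M and mitosis genes had a median of -0.35, with 28 of 30 lower, against 0.01 with siRNA1. Replication genes had 27 of 28 lower with siRNA2 and 16 of 28 with siRNA1. The kinesin KIF2C had ratios of -0.40 and -0.89 with siRNA1 and siRNA2, the phosphatase CDC25C -0.34 and -0.72, the replication licensing factor CDC6 -0.42 and -1.10, and thymidylate synthase, TYMS, -0.34 and -0.53. The other CDC6 probe set gave 0.22 and -0.28. Histone genes had a median of 1.15 with siRNA2, with 5 of 10 at least 2-fold higher, against 0.04 with siRNA1. By the mean they were at 1.01 and 0.28, outside the random lists with both siRNAs. H2BC5 was 2.71-fold higher with siRNA1 and 5.28-fold with siRNA2, H2AC6 had ratios of 1.00 and 2.20 and H2BC12 0.54 and 1.36. The variant histone H2AX had -0.30 and -0.54, but 0.04 with siRNA1 by the median over its probe sets, and the variant H2AZ1, chosen after its values were seen, had -0.07 and -0.22.

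TGF-beta targets had a median of 0.44 with siRNA2, with 11 of 15 higher, and 0.00 with siRNA1. In that list ID2, an inhibitor of helix-loop-helix factors, was 2.39-fold and 2.33-fold higher, ID3 had ratios of 1.01 and 0.99, LTBP2, a TGF-beta binding matrix protein, was 2.89-fold and 2.23-fold lower (-0.97 with siRNA2 by the median over its probe sets), and SMAD3 had -1.35 and -0.57. Mesenchymal genes had a median of 0.25 with siRNA2 and -0.16 with siRNA1, and FN1, fibronectin, had ratios of 0.16 and 0.70. Nuclear-encoded respiratory chain genes had medians of 0.05 with siRNA1, where the mean was -0.04, and 0.16 with siRNA2. Ribosomal protein genes had medians of 0.02 and 0.00, and housekeeping genes -0.06 and -0.02. By the mean, housekeeping genes were at -0.19 with siRNA1, outside the random lists, and at -0.13 with siRNA2, inside them.

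**Figure D4:**
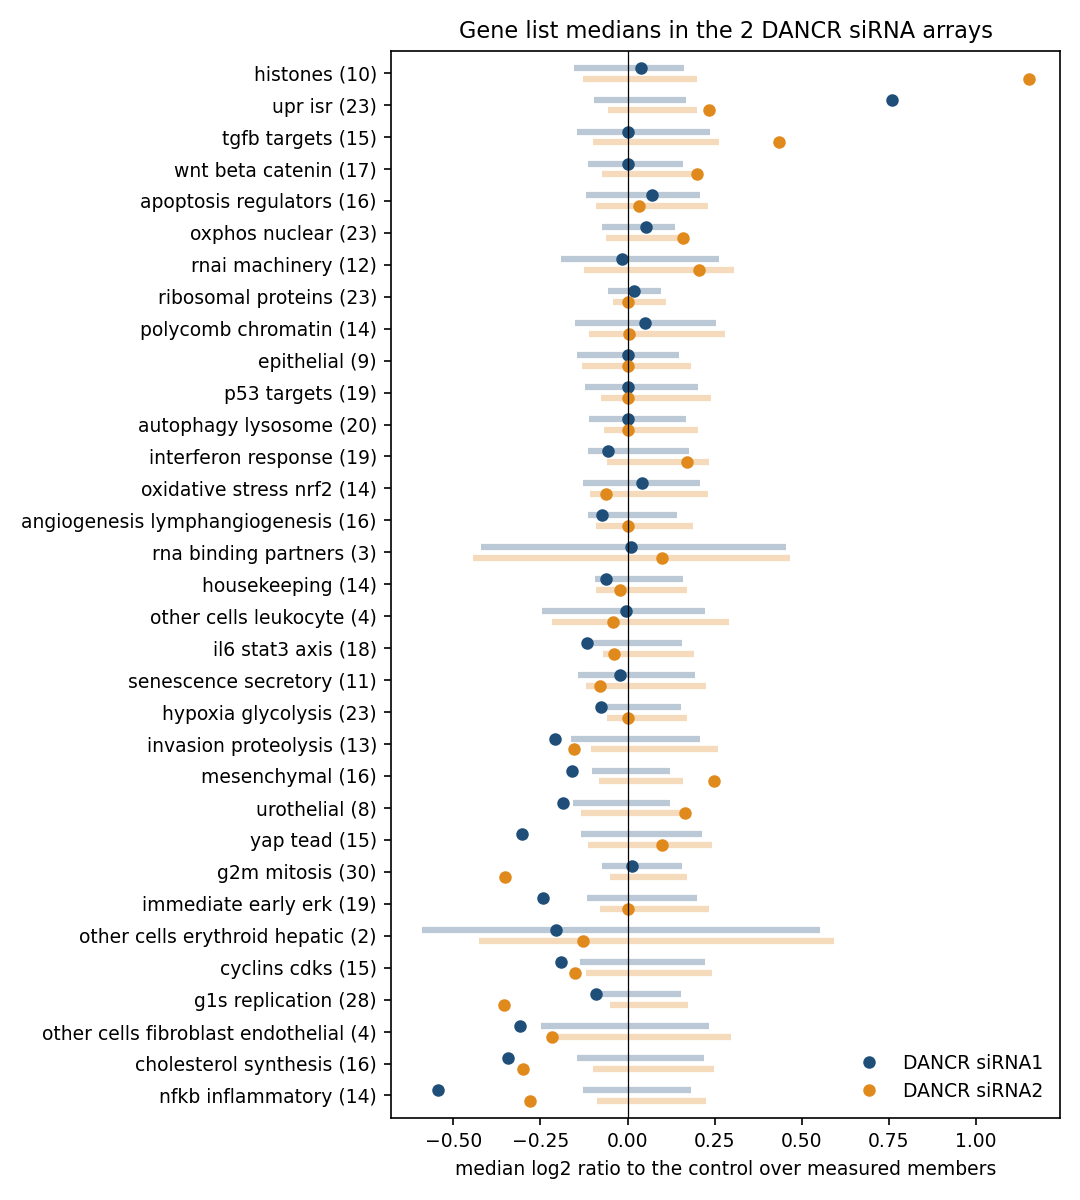
Median log2 ratio to the control (x axis) over the measured members of each gene list (y axis, number of members in brackets) with siRNA1 (blue) and siRNA2 (orange). Pale bars span the central 95% of 10000 matched random lists. Histone genes lie at 0.04 and 1.15 and stress response genes at 0.76 and 0.23, and the list of study targets (-2.50 and -1.95) is left off.

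The fourth comparison set siRNA1 against siRNA2, both aimed at DANCR. DANCR itself differed by 1.08-fold. CDK6, a kinase that cyclin D binds, was 6.17-fold lower with siRNA1 than with siRNA2, at 184 against 1137, with 316 in the control. GCH1, which starts tetrahydrobiopterin synthesis, was 4.46-fold lower with siRNA1, and the chromatin protein HMGB3 was 7.80-fold higher with siRNA1, at 581 against 74.5, with 440 in the control. STT3B, a subunit that transfers N-glycans, was 5.95-fold higher with siRNA1 than with siRNA2, at 436 against 73.3, with 388 in the control. SLC7A11, the cystine transporter, was 5.20-fold higher, at 346 against 66.5, with 90.5 in the control. CCND1 was 4.47-fold higher with siRNA1.

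In all, 487 genes were 2-fold apart between the siRNA arrays, 188 higher and 299 lower with siRNA1. That was more than the 450 between siRNA1 and the control or the 418 between siRNA2 and the control. The simulation gave 424 (384 to 466), but its spread was taken from this same difference, so it is no yardstick for this count. FAM210B was 5.58-fold lower with siRNA1 than with siRNA2, at 26.5 against 148, with 40.5 in the control. VARS1, the valyl-tRNA synthetase, was 4.20-fold lower, at 43.1 against 181, with 148 in the control. TIGD1 was 4.17-fold lower, at 16.9 against 70.3, with 22.2 in the control. DNAJC6, an auxilin of clathrin uncoating, was 5.29-fold higher with siRNA1 and MORF4L1, a chromatin reader, 4.94-fold. The 2 brightest further probe sets of CDK6 gave 2.01 and 1.87 (log2) with siRNA2, while those of MORF4L1 gave -0.10 and -0.34, against -1.85, and that of VARS1 gave -0.17 with siRNA1. The second HMGB3 probe set gave -1.15 with siRNA1 and -2.26 with siRNA2.

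The medians of 12 lists lay outside the random lists in this comparison. Stress response genes differed by 0.46, mitosis genes by 0.41 and replication genes by 0.34, all higher with siRNA1. Lower with siRNA1 were histone genes (-0.95), urothelial markers (-0.51), YAP/TEAD targets (-0.43), mesenchymal genes (-0.40), TGF-beta targets (-0.38), interferon-response genes (-0.25), NF-kappaB targets (-0.21), the study targets (-1.32) and fibroblast and endothelial markers (-0.47). By the mean of members, NF-kappaB targets (-0.21) and the study targets (-0.20) lay inside the random lists. The median of the study targets is the value of IL11, at the floor with siRNA1, and CCND1 differed the other way by 2.16. Markers of cells that the culture should not hold were all of low intensity. The endothelial receptor TIE1 was at 30.9, 10.1 and 19.5, the B-cell marker CD79A at 23.0, 22.9 and 18.9 and the hepatic marker TTR at 24.9, 20.8 and 21.9. The fibroblast and endothelial list had medians of -0.31 and -0.22, the leukocyte list -0.00 and -0.04, and the erythroid and hepatic list -0.20 and -0.13.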

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

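No test in this part was chosen after its result was seen, though the genes and probe sets named here were picked from their values. SLC35F5, a solute carrier family member, was the only gene at least 2-fold higher with DANCR siRNA1 and at least 2-fold lower with DANCR siRNA2, so the count of genes 2-fold in opposite directions was 1. Its intensity was 53.4 in the control, 112 with siRNA1 and 24.1 with siRNA2, log2 ratios of 1.07 and -1.15. The difference of 2.21 was not tested, because each group had 1 array.

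Among 3670 probe sets above the floor that the annotation assigns to no gene, and which no comparison of the report uses, 10 were at least 2-fold higher and 5 at least 2-fold lower with both siRNAs than in the control. In the control, siRNA1 and siRNA2 arrays, the higher probe sets with the strongest control signal were at 303, 787 and 615 and at 207, 496 and 535, and the lower probe set with the strongest control signal was at 494, 122 and 174. They share the control array with every other ratio here, and no explanation was tested for them.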

How the results depend on the processing

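The mean of a list's members in place of the median was chosen only after the data were seen, and the other alternatives were planned. DANCR kept its direction and 2-fold difference under every alternative that recomputed it. The genes called in both siRNAs were 124 under median-centring, all 124 of them in the main set, and 109 of 113 under quantile normalisation. With floors at the 30th and 70th percentile and with no floor, 124 of 131, 91 of 91 and 124 of 134 were in the main set. With the median over probe sets 82 of 84 were, and without _s_at and _x_at probe sets 87 of 91. In all these settings the control array stood apart in no more than 1.5 times as many genes as either siRNA array. The median over probe sets gave 54 genes higher in both and 148 higher with siRNA1. A threshold of 1.5-fold gave 435 higher and 161 lower in both, 888 and 750 with siRNA1, 1088 and 533 with siRNA2 and 1714 between the siRNAs. A threshold of 3-fold gave 6, 6, 24, 36, 34, 34 and 77 in the same order. Limma with the siRNA arrays as replicates, on 1 residual degree of freedom, called 0 higher and 0 lower at an adjusted p of 0.05 (smallest 0.214). At an unadjusted p under 0.05 it gave 901 and 798, and on simulated data it also recovered 0 planted genes after adjustment.

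A list was called when it lay outside the random lists with each siRNA, and the values here are its medians in the mean of both. Fibroblast and endothelial markers (-0.26 in the main setting) became called under quantile normalisation (-0.28) and the median over probe sets (-0.26). Stress response genes were no longer called under the median over probe sets (0.48) or without _s_at and _x_at probe sets (0.53), where cyclins (-0.19), replication (-0.14) and proteases (-0.0209) also ended. By the mean of members, the replication call ended with siRNA1 (-0.24 in the mean of both) and histones became called (0.64). The cause was not tested. No list called in the report and no named gene value at 2-fold reversed. The higher floor at the 70th percentile took COL3A1, ECSCR, P2RY8, SAMSN1 and WIPI1 below 2-fold. Of 1968 values of named genes, DANCR included, 118 moved by more than the spread and 8 changed sign. CDC6 with siRNA1 became 0.22 and IDI1 with siRNA2 0.09 without _s_at and _x_at probe sets. HMGB3 and H2AX with siRNA1 became -0.37 and 0.04 with the median over probe sets, and WDR5 with siRNA1 became -0.02 under quantile normalisation; the other 3 belong to genes that the text does not describe. No paired analysis was possible because each group had 1 array, and no array could be left out in turn. Signal over background limits genes near the floor of 10.5, where ratios are bounds.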

Other observations

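The comparison of odd-array counts, both tests of the siRNA2 lists and the control-level test of stress response genes were chosen only after their results were seen. None of the gene groups in this and the next paragraph had a median outside the random lists on the same side with both siRNAs. Cytokines, receptors, STAT3 and targets of the interleukin 6 axis had medians of -0.12 with siRNA1, outside the random lists, and -0.04 with siRNA2, inside them. In that axis SOCS1, a feedback inhibitor, had log2 ratios of -1.16 and -0.87 and the cytokine LIF -0.93 and -0.76, while CEBPD had 1.06 and 0.79. SOCS1 was at 27.2, 12.2 and 14.9, and its other probe sets, near the floor, gave 0.10 and 0.00, and 0.00 with both. STAT3 itself, named after its values were seen, was at 159, 94.5 and 259. Interferon-response genes, which double-stranded RNA can induce, had medians of -0.05 and 0.17, with IFI44 at 0.79 and 0.33 and OAS3 at -0.60 and -0.49. The RNA interference machinery had medians of -0.01 and 0.20. Of p53 targets, with medians of 0.00 and 0.00, GADD45A had -0.71 and -0.53 and TP53I3 0.62 and 0.48. Apoptosis regulators had medians of 0.07 and 0.03.

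Wnt targets had medians of 0.00 and 0.20, the latter with a mean of -0.06, and LEF1, a transcription factor of that pathway, had ratios of -1.43 and -0.53. Urothelial markers had medians of -0.18 with siRNA1, outside the random lists, and 0.16 with siRNA2, with FGFR3 at 0.46 and 0.97. Epithelial genes had 0.00 and 0.00, with KRT18, an intermediate filament gene, at -0.89 and -0.36. Angiogenic factors had -0.07 and 0.00, with ANGPTL4 at -0.57 and -0.70 but ANGPT1 at 0.60 and 0.48. Hypoxia and glycolysis genes had -0.08 and 0.00, with PFKFB4 at -1.03 and -0.74. Polycomb and SWI/SNF subunits had 0.05 and 0.01, with the methyltransferase EZH2 at -0.42 and -0.85 and JARID2 at 0.63 and 1.67. NRF2 targets had 0.04 and -0.06, with TXNRD1, a thioredoxin reductase, at -0.56 and -0.66 but ME1 at 0.65 and 0.82. Autophagy and lysosome genes had 0.00 and 0.00, with WIPI1 2.11-fold and 2.86-fold higher, but at 0.78 (log2) with siRNA1 by the median over its probe sets and 0.48 without _s_at and _x_at probe sets. Secreted factors of senescent cells had -0.02 and -0.08, the latter with a mean of 0.08, and IGFBP3 was at 70.2, 134 and 405.

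The 124 genes 2-fold from the control in both siRNA arrays may partly reflect a deviation of the control array of the size that the other arrays show, since its count was 0.943 times the mean count of the siRNA arrays. Errors of single probe sets are argued against as the source of the shared direction. Second probe sets of 68 called genes had a median of 0.63 in the called direction, with 58 of 68 on the same side. Only 22 of 68 reached 2-fold, so for most of these genes the second probe set did not bear out the 2-fold size. Genes in which siRNA1 stood apart had a second probe set median of 0.68, with 65 of 75 on the same side. Where siRNA2 stood apart these were 0.83 and 62 of 75, so such agreement was not particular to the genes shared by both siRNAs. Simulated unchanged arrays gave a median of 117 such genes, but the match of totals decides nothing, since higher genes lay above the simulated count (89 against 54) and lower genes below it (35 against 64). The simulated spread includes true differences between the siRNAs, yet it gave 424 genes apart between them where 487 were seen, and fewer genes with the same sign (68.4% against 70.6%). A deviation of the control array, the spread of single arrays and an effect of DANCR loss all stay open for any single gene other than DANCR. DANCR is the target and was named in advance, and it is 1 of only 2 genes with the control at least 4-fold above both other arrays.

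Lower replication and mitosis genes and higher histone genes with siRNA2 were followed next. All 3 medians lay at least 0.30 (log2) beyond the range of random lists of like intensity, in opposite directions. Genes of like intensity thus did not move with them. The lists were picked on these same medians, so this is no independent evidence against a dimmer siRNA2 array. A level of the control array alone cannot give a difference between siRNA1 and siRNA2, which was at least 0.34 in the 3 lists. That difference, too, was part of how the lists were picked. RNA quality stays open, since the 3'/5' ratio of ACTB was 14.4 on the siRNA2 array against 11.9 and 11.8. A lower proliferation rate, an off-target effect of its sequence or a state of that 1 culture could each give this pattern, and none was tested.

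Higher stress response genes with siRNA1 were the last pattern weighed. A level of the control array alone cannot give the difference of 0.46 between the siRNAs. This check was chosen after its result was seen, so it is no independent support. Errors of single probe sets cannot be told apart from a change of the RNA, because second probe sets of 12 members had a median of 0.24 with siRNA1, between the bounds set in advance for each reading; with siRNA2 it was 0. An off-target effect of siRNA1 or a state of that culture could also give this pattern and was not tested.

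A further hypothesis held that genes whose symbol starts with ZNF shift together. Their 338 measured members had medians of 0.14 and 0.09, at percentile 100 of matched random lists. The test by the median decides nothing, because the random medians were nearly all 0 and any higher median would lie there. By the mean of members, which is not bound to 0 in this way, they were at 0.27 and 0.21. Those means also lay at percentile 100 with each siRNA. Of ZNF genes, 50.6% were higher and 9.76% lower with both siRNAs, against 29.2% and 23.7% of measured genes. At 2-fold, 8 ZNF genes were higher with both siRNAs, 9 lay above both other arrays with siRNA1 and 1 with siRNA2. As a group, ZNF genes thus lay higher in both siRNA arrays than in this control array. Whether that is a shared shift of the family or a level of the control array stays open. Another hypothesis, that lower DANCR belongs to a change of its chromosome region, was argued against. The 10 nearest measured genes had a median of 0.07, at percentile 78.8 of such runs.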
